A study of Canis lupus familiaris with 2 samples.

How the data were processed

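Whole-genome bisulfite sequencing was done on 2 cultures of MDCK cells, an epithelial line from dog kidney. Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine in place, so each read base over a CpG cytosine is a methylated or an unmethylated call. Per the labels, the control culture was untreated and was kept for 30 days beside a culture given TGF-beta at 5 ng/ml, and each group has 1 library. Groups were taken from the labelled agent. Per the labels' protocols, DNA was sheared by sonication, ligated to methylated adapters, bisulfite converted, size-selected on a gel and amplified by PCR before paired-end sequencing.

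The deposited values are counts: for each listed CpG cytosine, the authors' files give a count of methylated calls and a count of unmethylated calls, with the strands on separate lines and no header. Bismark and Bowtie 0.12.8 with the canFam3 build are named in the submitters' processing notes, whereas the labels' extraction protocol names SOAPaligner2, so the sources differ on the aligner. Removal of PCR duplicates, quality filters and the trimming of overlapping mates are not given in the sources used here. Read mates that overlap, or duplicates that were kept, would make calls depend on each other and would make any interval from counts too narrow. Which column holds methylated calls was decided from the values, since mitochondrial DNA is almost free of the first kind of call. In each file 1 line names no chromosome, with 12 calls in the control and 6 in the TGF-beta library, and these were left out.

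Adjacent cytosines were joined into CpG sites, which gave 25888236 sites, 90.6% of them with both strands listed. Cytosines in runs that could not be paired held 0.00656% of the calls and were left out. Sites needed at least 5 calls in both libraries, and tests of single sites needed 10. The level of a region is its methylated calls over all its calls, summed over sites. Because summed calls weight each site by its depth, the unweighted mean of site levels is given beside it for the main comparisons. That was planned for the genome difference and added after the data were examined for windows, CpG-dense windows and domains.

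Each window of 1000 bp with at least 5 sites was tested with a two-sided Fisher's exact test on summed calls, adjusted by Benjamini and Hochberg's method over all windows. A window was called at an adjusted p under 0.05 in that exact test and a difference of at least 20 percentage points. Single sites were called by the same limits. CpG-dense windows, with at least 40 listed sites, stood in for CpG islands, as planned for the case without a genome sequence of the build. Domains of 100 kb needed 50 sites and were compared without a test, with counts of those that differed by 10 points or more. Tests on reads compare these 2 libraries, not the conditions, and no test across replicates exists.

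The strands of a CpG are read from different molecules, so a comparison of strands within a library shows technical spread. Overdispersion was the mean over windows of the squared strand difference divided by its binomial expectation, in windows with at least 30 calls per strand and a level between 10% and 90%. The half-difference of the strands, 0.5 times the difference between their library differences, has the sampling noise of their mean, if strands are sampled independently, and was counted past the same size as that mean, a comparison added after the data were examined. A score test with the variance of each library scaled by that factor was added after the data were examined. Depth along the genome was the log2 ratio of TGF-beta to control calls in bins of 1 Mb, over windows of 5 to 9 listed sites, regressed on CpG density. A depth segment was a stretch of at least 10 bins whose running median over 5 bins departed by 0.35 or more.

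The windows named in the text are the 5 with the largest gain and the 5 with the largest loss among called windows with at least 10 sites, at least 200 calls in each library, and 10 points of difference in the same direction on each strand. That rule was fixed before the data were examined. Named CpG-dense windows, runs of windows and runs of domains were picked after their values were seen. Gene promoters, gene lists and named genes were planned and are not analysed here, because no annotation of canFam3 was used and coordinates of another build cannot be mixed with it.

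Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9. The window test was tested on simulated data, with 100000 windows at the real depths and control levels and 200 of them changed. With binomial calls, 48.5% of windows changed by 20 points were called, 97.5% at 30 points and 99.0% at 40 points, and 1 unchanged window or none was called in each simulation. The rule itself needs an observed difference of 20 points, so the shares at 20 points largely reflect that threshold. With binomial calls, 162 of the 200 windows changed by 20 points passed the test alone. With calls overdispersed by factors of 3 in the control and 6 in the TGF-beta library, 56.0%, 88.0% and 97.5% were called, but so were 2163, 2283 and 2278 unchanged windows. The scaled score test called 1, 3 and 5 unchanged windows in the same simulations and recovered 27, 105 and 137 of the 200 changed ones. With factors of 2.5 and 4, near those from medians, 47.5%, 92.5% and 99.0% of changed windows were called, along with 1055, 1081 and 1153 unchanged ones. Fisher's exact test matched scipy's in 2000 of 2000 simulated tables within 1e-09.

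Alternatives covered the coverage minimum, sites of very high coverage, thinning of the deeper library, autosomes alone, window size, the size threshold, an exact sign test over sites, a requirement on each strand, centring, and the weighting of sites.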

Results

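The series compared the DNA methylation of MDCK cells, a dog kidney epithelial line, without treatment and after 30 days with TGF-beta at 5 ng/ml. TGF-beta is a growth factor that drives epithelial cells towards a mesenchymal state, and the labels describe the control as epithelial and the treated culture as mesenchymal. There was 1 library per group, so no difference below has a replicate check. The control library held 656122583 calls over 47583802 cytosines and the TGF-beta library 1019766599 calls over 46385052. At least 5 calls in both libraries were present at 22984712 CpG sites, 88.8% of those listed, with a median of 22 calls per site in the control and 38 in the TGF-beta library. Intervals are exact 95% binomial intervals and cover counting error only. Positions are in canFam3, and gene annotation is not used here.

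The first comparison asks whether the average methylation of the genome differed. It was close in the 2 libraries. The mean of site levels was 63.7% in the control and 64.0% in the TGF-beta library, higher by 0.341 percentage points, and it was higher in the TGF-beta library on 36 of 38 autosomes, over a range of -0.511 to 1.18 points. On chromosome X it was lower, at 55.4% against 56.1%. Summed calls gave 65.6% (65.6 to 65.6) in the control and 66.1% (66.1 to 66.1) in the TGF-beta library, a difference of 0.518 points. That value depended on which sites were counted, at 1.56 points on autosomes and -11.4 points on unplaced sequences, and on chromosome X summed calls gave 3.38 points, opposite in sign to the mean of site levels. At sites with enough calls on a single strand, summed calls differed by 0.386 points on the plus strand and -0.0461 on the minus strand, and means of site levels by 0.392 and 0.385.

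**Figure D1:**
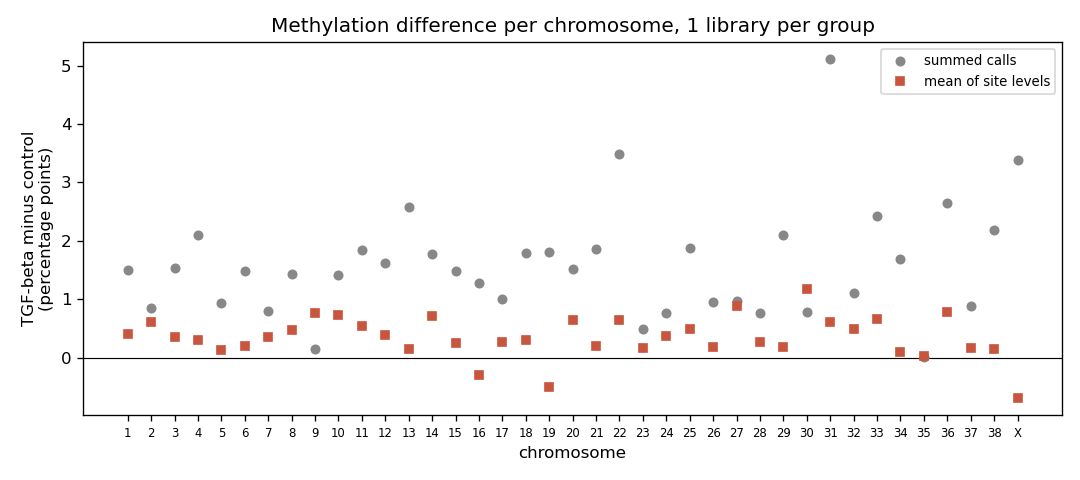
Difference in methylation (TGF-beta minus control, percentage points, vertical axis) for each chromosome (horizontal axis), from summed calls (grey circles) and from the mean of site levels (red squares), with 1 library per group. Summed calls reached 5.11 points on an autosome, while the mean of site levels stayed between -0.511 and 1.18 points on autosomes.

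The libraries covered CpG-dense sequence and some chromosome parts unequally. The ratio of TGF-beta to control calls rose from 0.954 in windows of 1 to 4 listed sites to 1.92 in windows of 40 or more. Within windows of 1 to 4, 5 to 9, 10 to 19 and 20 to 39 listed sites, summed levels differed by -0.266, 0.281, -0.00866 and -0.236 points, and means of site levels by 0.618, 0.256, 0.109 and 0.171 points, opposite in sign in 3 of these 4 classes. In the densest class they differed by -2.90 points, against 0.841 points by the mean of site levels. Mitochondrial DNA, used as an upper bound on failed conversion, was at 0.211% (0.205 to 0.217) in the control and 0.329% (0.325 to 0.334) in the TGF-beta library. At the first position of its CpG pairs alone it was at 0.635% and 1.01%, so the bound is looser there.

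**Figure D2:**
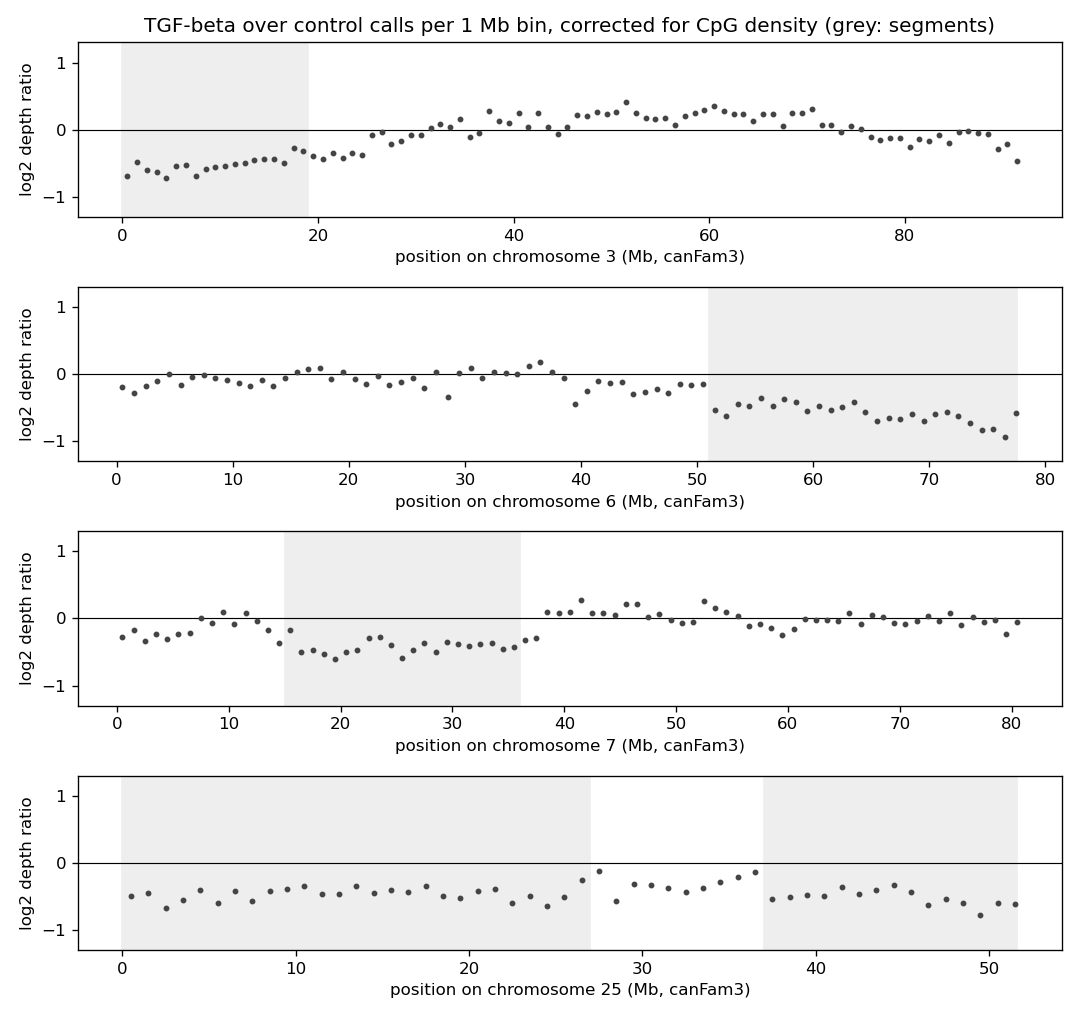
Log2 ratio of TGF-beta to control calls after correction for CpG density (vertical axis) in bins of 1 Mb along chromosomes 3, 6, 7 and 25 (Mb, horizontal axis), with 1 library per group. The ratio had a median of -0.57 on chromosome 6 from 51000001 to 77573627 and -0.45 over the whole of chromosome 25.

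Slightly fewer sites had intermediate levels, and slightly more had high levels, in the TGF-beta library. Among 19700914 sites with at least 10 calls in both libraries, those between 20% and 80% made up 28.1% in the control and 27.4% in the TGF-beta library, and those at 80% or more made up 52.5% and 53.3%. The share under 20% was 19.3% and 19.4%. The median depth of these sites was 25 calls in the control and 42 in the TGF-beta library, which affects such shares. With the calls of each site drawn to the smaller count, the shares differed by 0.174 points under 20%, -0.968 points between 20% and 80% and 0.794 points at 80% or more. Sites at exactly 100% made up 12.9% in the control and 8.56% in the TGF-beta library at their own depths, but 14.03% and 15.8% at equal calls per site. Fisher's exact test called 245199 sites higher and 214532 lower in the TGF-beta library.

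Long blocks differed between the cultures. The longest, on chromosome 27 from 22700001 to 24100000, was at 49.6% (49.4 to 49.9) in the control and 71.5% (71.3 to 71.7) in the TGF-beta library, over 5643 sites with 214220 and 200099 calls. On chromosome 34 from 35400001 to 35900000 the level was 58.2% (58.0 to 58.5) against 85.4% (85.3 to 85.5), and 334 of 434 tested windows were called higher and 1 lower. On chromosome 15 from 53700001 to 54600000 it was 48.2% against 68.6%, and on chromosome 1 from 19900001 to 20500000 it was 49.0% against 68.4%. In the other direction, chromosome 20 from 10200001 to 10900000 was at 77.7% (77.4 to 77.9) in the control and 58.1% (57.8 to 58.4) in the TGF-beta library, and chromosome 19 from 35400001 to 36000000 was at 82.1% against 68.3%.

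By the mean of site levels these blocks differed by similar amounts: 20.5 points on chromosome 27, 25.2 on chromosome 34, 19.2 on chromosome 15, 17.9 on chromosome 1, -20.8 on chromosome 20 and -13.5 on chromosome 19. At least 3 adjacent domains of 100 kb were higher by 10 points or more in 47 places and lower in 15, with at least 5 points in the same direction on each strand. When the positions of such domains were shuffled within chromosomes 100 times, the mean was 0.41 and 0.09 places. The shuffles treat neighbouring domains as exchangeable, so they show that such domains cluster and not why. With the size threshold alone, comparing the strands within either library gave 0 places, whereas comparing the libraries gave 34 higher and 13 lower on the plus strand alone and 37 and 10 on the minus strand alone. By the mean of site levels over each place, 40 of the 47 higher and 13 of the 15 lower kept 10 points or more. Runs of at least 3 domains that each differed by 10 points by mean site level numbered 31 higher and 14 lower.

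**Figure D3:**
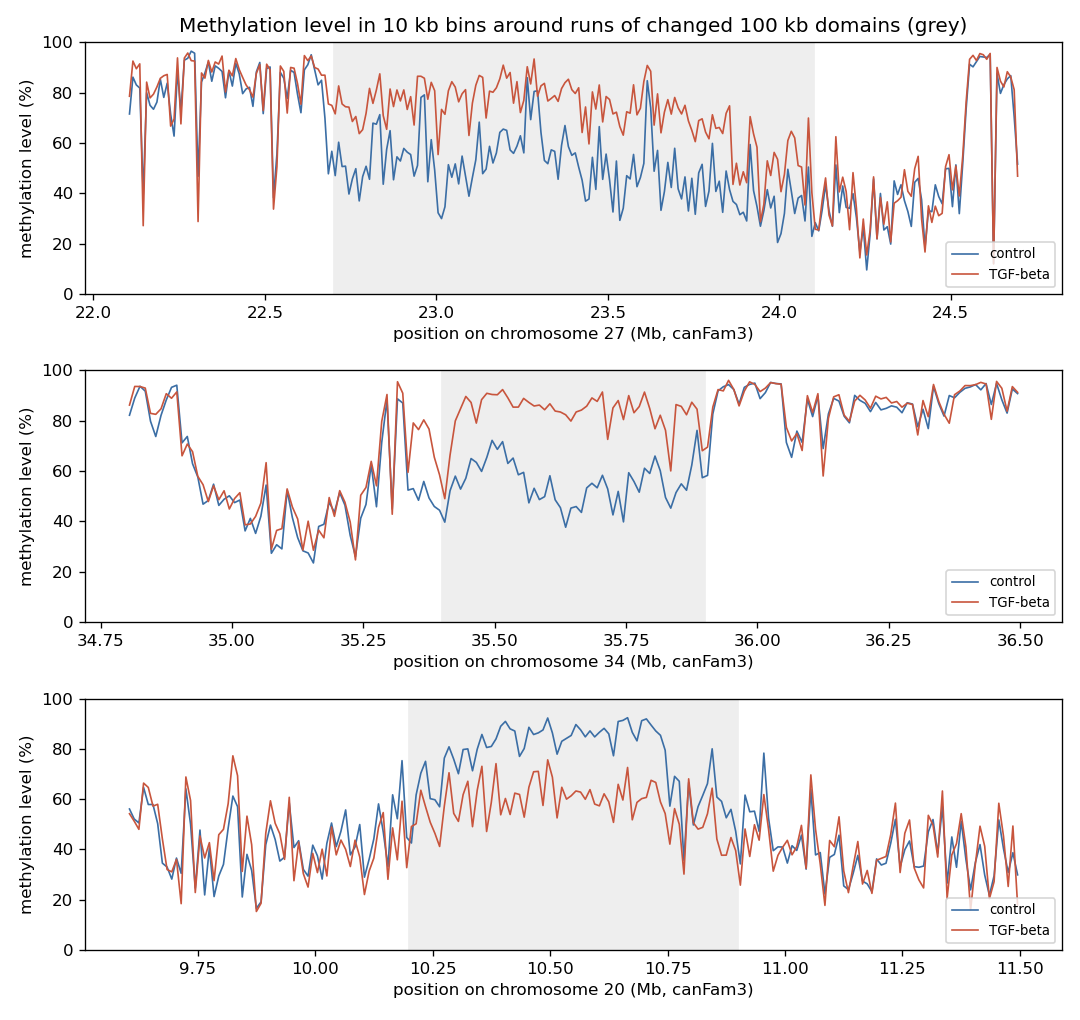
Methylation level (%, vertical axis) in bins of 10 kb along chromosomes 27, 34 and 20 (Mb, horizontal axis) in the control (blue) and TGF-beta (red) libraries, with the run of changed domains in grey. The TGF-beta library lies above the control in the grey part on chromosomes 27 and 34 and below it on chromosome 20, where the summed levels were 77.7% and 58.1%.

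Over all 23275 domains the levels of the libraries were closely related (r = 0.976 across domains, which are not independent replicates). The median difference was 0.715 points (quartiles -1.24 and 2.82), 541 domains were higher by 10 points or more and 339 were lower. The 538 higher domains that held on both strands had a median of 49.6% in the control and 64.3% in the TGF-beta library, and the 335 lower ones 72.0% and 59.5%. These levels come from the calls that selected the domains. With sites weighted equally 294 domains were higher and 139 lower. Of the 335 lower domains only 174 kept their sign and 108 kept 10 points, against 518 and 284 of the 538 higher ones. With sites covered on each strand, the strands of the control differed by 10 points or more in 173 of 22914 domains and those of the TGF-beta library in 648, against 1182 between the libraries on the plus strand. The libraries differed by 10 points or more in the same direction on each strand in 602 domains and in opposite directions in 0, and the mean of the strands' differences reached 10 points in 946 domains, against 6 for their half-difference.

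**Figure D4:**
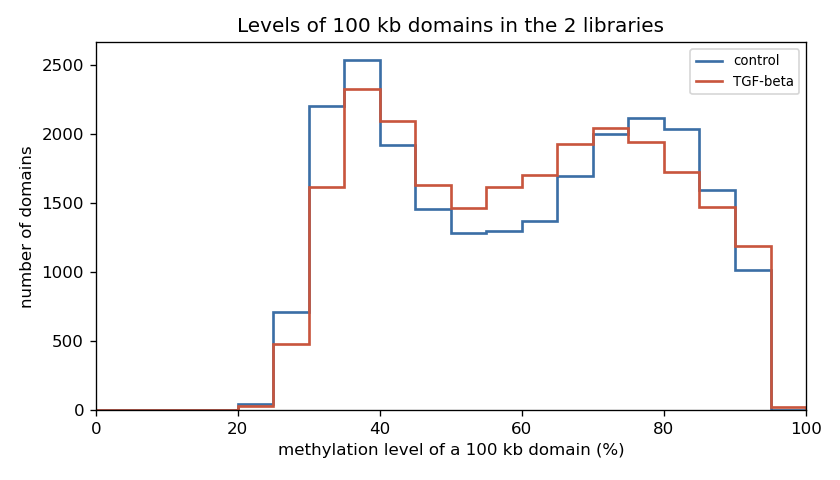
Number of 100 kb domains (vertical axis) at each methylation level (%, horizontal axis, summed calls) in the control (blue) and TGF-beta (red) libraries. The share of domains under 50% was 38.1% in the control and 35.1% in the TGF-beta library, and the share at 80% or more was 19.9% and 18.9%.

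At the scale of 1000 bp, more windows were higher than lower in the TGF-beta library. Of 1497941 windows tested with Fisher's exact test, 33200 (2.22%) were called higher and 21443 (1.43%) lower. Among windows that met the rule for naming, the largest gains were on chromosome 14 at 40417001 to 40418000, from 10.2% (8.04 to 12.8, 664 calls) to 76.8% (74.5 to 79.0, 1397 calls), and on chromosome 6 at 18193001 to 18194000, from 5.07% (3.24 to 7.50) to 71.3% (67.0 to 75.2). The others were on chromosome 9 at 4613001, from 14.2% to 79.0%, and at 32108001, from 29.9% to 94.5%, and on chromosome 7 at 6165001, from 21.2% to 85.4%. The largest losses were on chromosome 35 at 12895001 to 12896000, from 95.8% (92.1 to 98.0, 212 calls) to 20.3% (16.9 to 23.9, 533 calls), and on chromosome 31 at 30356001 to 30357000, from 91.6% (89.1 to 93.8) to 16.2% (14.3 to 18.3). The others were on chromosome 10 at 20428001, from 77.1% to 6.60%, on chromosome 2 at 54556001, from 83.6% to 18.5%, and on chromosome 24 at 39661001, from 87.6% to 22.6%. By the mean of site levels the 5 losses were smaller, between -52.1 and -65.9 points.

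Large differences between the libraries were more often shared than opposed by the strands, but not each called window is a window that changed. Over the 625852 windows with sites covered on each strand, the library differences of the strands were only partly related (r = 0.40 across windows). Over all 1497941 windows, with no minimum of calls per strand, the strands differed by 20 points or more in the same direction in 23529. They did so in opposite directions in 3515. Among the 625852 windows, the mean of the strands' differences reached 20 points in 13417. Their half-difference, which carries the same sampling noise and no change that the strands share, did so in 1314. In those 625852 windows the exact test called 13009 between the strands of the control and 24492 between those of the TGF-beta library. It called 21409 and 21536 between the libraries on the same strand and 36257 and 36139 on opposite strands. Differences between strands were partly shared by the libraries (r = 0.35 across windows, which are not independent replicates), so they are not sampling alone. The variance between strands was on average 2.99 times the binomial one in the control and 5.87 times in the TGF-beta library, or 2.46 and 4.09 times as estimated from medians over windows. In simulated windows with about the average variance 2.17% to 2.29% of unchanged windows were called, and with about the variance from medians 1.06% to 1.16%. These simulations drew all of that variance as separate noise in each library. The libraries partly share it, so these percentages may be too high. The factors come from differences between strands and leave out technical variance that the strands share, so the percentages may also be too low. In the data 2.22% of windows were called higher and 1.43% lower. With the average variance the score test called 9044 windows higher and 3869 lower. Of the windows called by Fisher's exact test, 12890 higher and 6818 lower ones also differed by 20 points by the mean of site levels.

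Among the 24748 higher windows that held on both strands, the median was 40.9% in the control and 69.2% in the TGF-beta library, and 618 went from under 20% to 50% or more. Among the 15111 lower ones the median was 61.9% and 35.2%, and 324 went from 80% or more to under 50%. These levels come from the calls that selected the windows, and a window above 80% cannot gain 20 points. Windows classed by level on the plus strand had median differences on the minus strand of 0.155, -0.0710, -0.588, -0.168, 0.397 and 0.437 points. The classes were under 10%, 10% to 20%, 20% to 40%, 40% to 60%, 60% to 80%, and 80% or more. Windows between 20% and 60% thus did not gain as a whole in this set, which held fewer windows than were tested above. Domains of 100 kb classed in the same way had median differences of 0.503, 1.06, 0.0138 and 0.464 points. Their classes were under 40%, 40% to 60%, 60% to 80%, and 80% or more. Runs of at least 3 adjacent windows called higher on both strands occurred 445 times, against a mean of 4.57 in 100 shuffles, and runs called lower 84 times, against 1.32. These shuffles, too, show clustering and not its cause. The longest run covered 16 windows on chromosome 34 from 35726001 to 35742000, at 50.2% (48.8 to 51.5) and 88.2% (87.5 to 88.8), within the block described above.

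CpG-dense windows, which stood in for CpG islands, were more often higher than lower where they were called. Their median level was 76.5% in the control and 77.3% in the TGF-beta library, so as a set they were largely methylated. Of 87796 tested, 364 (0.415%) were called higher and 117 (0.133%) lower in the exact test. The largest gain, on chromosome 31 at 33855001 to 33856000, went from 13.96% (12.2 to 15.9, 1397 calls) to 72.6% (71.2 to 74.1, 3749 calls). The second, on chromosome 5 at 56364001 to 56365000, went from 0.201% (0.0244 to 0.726, 993 calls) to 49.9% (47.9 to 51.8, 2598 calls), and the fourth, on chromosome 24 at 25981001 to 25982000, from 2.92% (1.88 to 4.32) to 48.9% (46.3 to 51.5). The third was on chromosome 30 at 37799001, from 17.9% to 66.8%, and the fifth on chromosome 27 at 2206001, from 12.9% to 57.1%. By the mean of site levels the 5 gains were 49.9, 49.5, 46.4, 47.8 and 39.7 points, in order of size by summed calls. The losses rested largely on how calls were spread over sites: of the 5 largest, 4 differed by between -0.493 and 2.44 points by the mean of site levels and the other, on chromosome 5 at 56260001, by -17.9 points. Among the 4 was chromosome 6 at 49673001, at 63.0% against 12.0% by summed calls and 16.0% against 16.1% by site levels. Requiring 20 points by the mean of site levels as well left 182 higher and 23 lower.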

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

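The tests on depth were chosen after the result was seen. Depth relative to the control was lower in the TGF-beta library over parts of 4 chromosomes, a signal in call depth itself. Depth sets the weight and precision of each site in the comparisons of levels. Whether the cause of the lower depth also changed levels was not tested. Windows inside these segments, pooled, were called more often, 2.90% higher and 1.97% lower, than other autosomal windows, 2.23% and 1.41%. Their strands also differed by 10 points or more in opposite directions more often, in 3.58% against 2.54%. In the same direction they did so in 10.4% against 8.38%. The higher share of calls was not seen in each segment. On chromosome 25 from 37000001, 0.875% were called higher and 1.16% lower on both strands, against 2.39% and 1.37% in the rest of that chromosome. That rest includes the other segment of chromosome 25 and was itself low in depth, at -0.43. Among the 1314434 other autosomal windows, 22066 were called higher and 13065 lower on both strands, so the 1.16% was not below their share. On chromosome 3 0.975% were called lower against 1.02% in the rest of that chromosome. The segment of chromosome 25 from 37000001 held 16.2 sites per kb, against 7.34 to 8.16 in the other segments. Genome-wide, windows of 5 to 9 listed sites were called higher in 3.21%, and those of 40 or more in 0.415%. The log2 ratio was -0.53 on chromosome 3 from 1 to 19000000, -0.57 on chromosome 6 from 51000001 to 77573627 and -0.43 on chromosome 7 from 15000001 to 36000000. It was -0.46 on chromosome 25 from 1 to 27000000 and -0.52 from 37000001 to 51628840, with -0.45 as the median of the whole chromosome.

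Coverage that follows CpG density was predicted to shrink these departures in denser windows, but in windows of 15 to 29 listed sites the smallest was -0.45. Each set of windows had been regressed on CpG density, and a density effect left over whole regions would show in both sets. The test thus cannot exclude this cause. A copy number that differs between the cultures may account for the departures, as both densities gave similar values. The rest of chromosomes 3, 6 and 7 also had a median departure of -0.0856 at most. The step between adjacent stretches of 5 bins at the edge on chromosome 6, -0.32 at 51000001, was matched or exceeded on 11 of 35 other chromosomes, and that on chromosome 7, 0.50 at 36000001, on 1 of 35, so the edge adds to this evidence on chromosome 7 alone. The largest step on chromosome 3 lay outside its segment, so the edge there was not compared. On chromosome 25 most of the chromosome was low, so it has no such reference. Its step at 37000001, -0.21, was matched or exceeded on 25 of 35 other chromosomes. Whole chromosomes without a segment departed too, with medians from -0.259 on chromosome 28 to 0.289 on chromosome 35. GC content beyond CpG density, and the order in which regions replicate, were not tested and stay open.

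Mitochondrial DNA took 0.682% of the calls in the TGF-beta library and 0.348% in the control.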

How the results depend on the processing

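The scaled score test, the requirement on mean site levels, the removal of depth segments, equal calls per site, and domains by mean site level or without sites of very high coverage were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Promoters, gene lists and named genes were not run under any setting, because no annotation of the build was used. More windows were higher than lower under each of the 15 alternatives run, with 56.1% to 86.9% of calls higher, and so were CpG-dense windows under each of 12, with 71.4% to 92.5%. Where no cause is given, the cause was not tested.

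The summed genome difference was 0.608 points at 3 calls, 0.301 at 10 calls, 1.42 without sites of very high coverage, 0.342 with the deeper library thinned, 1.56 on autosomes and 0.341 by the mean of site levels. A threshold of 10 points called 125796 windows higher and 98501 lower, and 3066 and 1176 CpG-dense windows, and one of 30 points 7388 and 3635, and 56 and 15, by construction. The exact sign test, which uses far fewer observations per window, called 852 and 128 windows, and 198 and 16 CpG-dense ones. The score test called 9044 and 3869 windows. Requiring 20 points by mean site level left 12890 and 6818 windows, and 182 and 23 CpG-dense ones. Windows of 2000 bp gave 12362 lower.

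The share of sites between 20% and 80% differed by -0.820 points at 5 calls and -0.537 at 20, and that of sites at 80% or more by 0.804 and 0.494. With equal calls per site the shares under 20%, between 20% and 80% and at 80% or more differed by 0.174, -0.968 and 0.794 points. With 20 kb domains the median difference was 0.824 points, 4.26% were higher by 10 points and 2.63% lower. Outside CpG-dense windows the median was 0.896 and 0.580% were lower. By mean site level the median was 0.212, with 1.26% higher and 0.597% lower. At 10 calls, levels in windows of 5 to 9, 10 to 19, 20 to 39 and 40 or more listed sites differed by 0.154, -0.165, -0.282 and -2.98 points. Of 20 named windows, 16 stayed called at 10 calls. The exceptions were CpG-dense losses: on chromosome 20 at 8132001 the difference turned to 4.65 points, on chromosome 15 at 29672001 it shrank to -0.845, and 2 had too few sites. The sites tested singly had a median of 25 calls in the control and 42 in the TGF-beta library, so they show only large differences.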

Other observations

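Of the tests below, those on read sampling, on the weighting of sites, on conversion and on chromosome X were chosen after results were seen. Low-methylated CpG-dense windows on chromosome X had a larger median difference than those on autosomes. Windows under 40% on the plus strand over both libraries were at a median of 17.6% in the control and 25.5% in the TGF-beta library on the minus strand over 263 windows of chromosome X, with a median difference of 5.10 points. The 13951 autosomal windows lay near the floor, at 1.94% and 2.83%, with a median difference of 0.242 points. At like levels, between 10% and 40%, the median difference was 7.60 points over 214 windows of chromosome X (quartiles -2.98 and 15.1) and 1.67 points over 4471 autosomal ones (quartiles -4.38 and 8.12), and by the mean of site levels 8.09 and 2.21 points. The difference between the chromosomes was not tested. With the strands exchanged the X-linked value under 40% was 5.05 points. With 10 calls per strand it was only 1.82 points over 73 windows (quartiles -3.84 and 10.8), against 0.228 points over 6257 autosomal ones. Long unmethylated valleys, with at least 5 adjacent windows under 10% on the plus strand, numbered 24 and on the minus strand were at a median of 0.546% and 0.978%, and none differed by 5 points. A valley with a large gain could fall out of that choice, so the lack of larger differences tells little. By sign, 18 of the 24 were higher in the TGF-beta library, with a median difference of 0.261 points. Mitochondrial levels differed in the same direction, by 0.118 points over all sites and 0.378 points at first positions. Unequal conversion is thus not excluded for the valleys, or for the 0.242 points of autosomal windows.

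Many domains of 100 kb differed by 10 points or more, and technical candidate explanations stay open for part of that count. For read sampling the first test came out in favour: the strands of the TGF-beta library differed by 10 points in 648 domains, more than 0.5 times the 1182 between the libraries on the plus strand, against 173 for the control. That test concerns single strands, whereas the domains were counted over both. In a test matched to that count, added later, the half-difference of the strands reached 10 points in 6 domains and their mean in 946, which argues against read sampling as the cause. Weighting of sites by their calls, which the strands can share, may account for part, as 44.5% of the domains kept 10 points by mean site level. Such domains were 1.48 times as frequent in the middle of the range of call ratios as outside it, which met the bound set beforehand against uneven coverage, but that bound was wrong because it looked at the total of a domain and not at how calls spread over its sites. It was set aside after the result on site weighting was seen. Segments of altered depth held 6.82% of these domains and 4.65% of all domains, and 5.55% of domains inside them differed by 10 points against 3.69% outside, which argues against them as the cause of most and leaves a small excess unexplained.

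Runs of at least 3 adjacent domains were looked at separately. Read sampling gave 0 such runs between the strands of a library, against 47 of both directions between the libraries on 1 strand, which argues against it. By mean site level over a whole run 85.5% of the runs kept 10 points, short of the bound set to exclude weighting. That is not comparable to the share of single domains. Runs of domains that each differed by 10 points by mean site level numbered 31 higher and 14 lower. Weighting stays open for part of the runs. A change in the treated culture is 1 hypothesis for these blocks, but drift between cultures kept apart for 30 days cannot be told apart from it with 1 library per group.

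The mean site level was higher in the TGF-beta library by 0.341 points. Incomplete conversion could add at most 0.137 points, if the largest mitochondrial difference, 0.378 points, measures it, which argues against it as the whole cause. Without sites of very high coverage the difference was 0.343 points, which argues against those sites. Other differences in library preparation or mapping were not tested, and neither was drift between the cultures.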
